A study of Mus musculus with 6 samples.

How the data were processed

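RNA from tumour-associated macrophages (TAMs) of mouse colorectal tumours was sequenced in 6 deposited libraries. TAMs are macrophages taken from a tumour. The cells came from BALB/c mice that were wild type (WT) or lacked the chemokine gene Ccl5 (CCL5-/-), and from 2 sort gates defined by the surface proteins CD11b and F4/80. The CD11b-high F4/80-low gate (F4/80low) had 2 WT and 2 CCL5-/- libraries. The CD11b-low F4/80-high gate (F4/80hi) had 1 library labelled WT and 1 labelled CCL5-/-. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with the Illumina TruSeq RNA LT v2 kit. Nothing in the labels says whether replicates came from separate mice or pools, so p-values measure the spread between these libraries, which may be technical.

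Genotype and gate were taken from the characteristics fields of each sample. For the F4/80hi libraries these fields and the sample titles disagree on the genotype, each title naming the other genotype. Groups follow the fields, and each such library is called by its label. The titles would turn the sign of every F4/80hi difference.

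The F4/80low count table, deposited by the authors, held whole-number read counts for 24391 gene rows, and no row lacked a gene name. A deposited table of the authors' comparison held counts divided by the authors' size factors (a normalised signal), the authors' log2 fold change and its standard error, a score (the test statistic), and the authors' p-value and adjusted p-value. Dividing the deposited counts by these values returned 1 constant factor per library. The F4/80hi table held the authors' FPKM (fragments scaled to transcript length and to the number mapped) with lower and upper bounds for 23284 gene rows. Per the submitters' processing notes, FastQC, cutadapt, STAR, HTSeq, DESeq2, bcl2fastq 2.17.1.14, TopHat2 2.1.1 and Cufflinks 2.2.1 were used, and several human and mouse builds are listed. Which tool and build made which table is not given in the sources used here. The loci in the FPKM table overlapped the GRCm38 gene body of GENCODE M21 for 99.06% of 20873 shared symbols, so GRCm38 coordinates are printed. Strand use in counting is not given, so overlapping and antisense genes cannot be separated, and members of near-identical gene families are uncertain.

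Total counts of the F4/80low libraries ranged from 9280635 to 22411342. Rn45s, the ribosomal RNA precursor, took a large share of 2 of them, which left between 3857011 and 22222208 counts for other genes. The depth behind the FPKM values is unknown, so no interval is given for them.

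Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, robust quasi-likelihood fit, two-sided F test), with Benjamini-Hochberg adjustment at 0.05 over 12710 genes. The standard error of a log2 fold change was its size divided by the square root of F. Gene levels are TMM-scaled CPM (counts scaled to library size). Because the ribosomal RNA share split the libraries by replicate number, each list that passed is also given within same-numbered pairs, as medians or as a tally, single genes are so given where stated, and the fit is given with a term for the replicate number. Both fits were tested on simulated counts with the library sizes of these libraries. The simulated means were those of each replicate number, shared by the genotypes except in the changed genes. The noise was that of the fit with the term. Pairing by number was thus built in, so the recovery cannot show which fit suits these data. Without the term, 0% of the genes changed 2-fold and 0% of those changed 4-fold were recovered. With it, 59% and 100% were recovered, and 7 of 166 calls were false.

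Before the data were examined, 35 gene lists were fixed (pathways, markers of other cell types, and RNA quality), and Ccl5 was left out of each. Lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation and with fry, and p-values were adjusted over the 33 lists tested. The genes named were chosen by a rule also fixed then. It took Ccl5, S100a8, S100a9, Ccr1 and Ccr3 whatever their values, and a further item it took is not reported here. It took the 10 highest and 10 lowest changes past the threshold. These needed a mean log2 CPM of at least 3 and non-overlapping groups, and clone-named models and pseudogenes were left out. Failing that, the rule took up to 5 genes per direction by smallest p, under the same limits apart from the threshold. It also took up to 4 members of each list of note by smallest p, and for F4/80hi the 10 highest and 10 lowest changes among genes with FPKM of at least 10 in either library and up to 3 members of each list. Genes called with the replicate term are named in addition, chosen after their values were seen.

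With 1 library per label there is no test for F4/80hi. Changes are log2((FPKM + 1)/(FPKM + 1)) over genes with FPKM of at least 1 in either library, a scale that understates changes of low genes. A list's median was placed among 10000 random lists of the same size, matched on expression in 20 bins. The 2 tables were made separately, so levels were not compared between them.

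Whether the 2 tables share reads was tested after the data were examined. For genes with 20 to 400 reads summed over a pair of F4/80low libraries, the split of the reads between the pair was compared with the split given by the F4/80hi ratio, scaled by 1 factor, as a chi-square value per gene. Independent reads give a median of at least 0.455, the median of a chi-square variable with 1 degree of freedom, however deep the FPKM libraries were. In simulation, new reads of the same RNA gave 0.922 at the same depth and 0.505 at 10 times the depth, and shared reads gave 0.051.

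Alternatives were other scaling factors (RLE, upper quartile), no filter and a stricter filter, DESeq2 1.42.0, limma-voom, the replicate term, each library left out, and for FPKM other pseudocounts, filters and centring. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.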

Results

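The series asked how loss of the chemokine CCL5 alters gene expression in 2 TAM populations of mouse colorectal tumours. Raw counts were analysed for 4 F4/80low libraries (2 WT and 2 CCL5-/-), and FPKM values for 2 F4/80hi libraries (1 labelled WT and 1 labelled CCL5-/-). Total counts were 9280635 and 22411342 for WT replicates 1 and 2, and 10494542 and 19073767 for CCL5-/- replicates 1 and 2.

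The 6 deposited libraries did not behave as 6 independent ones. The ratio between the F4/80hi libraries predicted how reads of single genes split between the replicate 1 libraries of F4/80low more closely than independent reads allow. Over 6670 genes with 20 to 400 reads the median chi-square was 0.334 (95% bootstrap interval 0.316 to 0.354), below the 0.455 that independent reads give at the least. It was above the 0.051 that simulated shared reads gave, a gap whose cause was not tested. The match was crosswise. The library labelled F4/80hi CCL5-/- paired with F4/80low WT replicate 1, and the library labelled F4/80hi WT paired with F4/80low CCL5-/- replicate 1. The other 11 ordered pairs of F4/80low libraries gave medians from 3.702 to 10.234. The albumin gene Alb is an example, with 653 reads in CCL5-/- replicate 1 and 0, 1 and 0 in the other F4/80low libraries, against 53.0 FPKM in the library labelled F4/80hi WT and a listed 0 in the other. The F4/80hi values therefore differed from the replicate 1 pair by less than the sampling noise and are counted as the same 2 libraries, so that 4 libraries are counted in all. They are reported below under their labels and not as a separate population. Which gate these 2 libraries came from is not settled, and the name F4/80low for replicate 1 follows its label. If they were F4/80hi cells, the replicate term would stand for the gate, and each genotype would have no replicate within a gate.

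The F4/80low libraries also split by replicate number. Rn45s, the ribosomal RNA precursor, took 58.4% of counts in WT replicate 1 (Wilson 95% interval 58.409 to 58.472, counting error only) and 50.035% in CCL5-/- replicate 1 (50.004 to 50.065), against 0.844% and 1.38% in the replicates 2 (0.84 to 0.848 and 1.377 to 1.388). The first principal component held 76.0% of the variance and separated the replicate numbers. With edgeR, 4047 genes differed between replicate numbers at an adjusted p under 0.05, 1763 higher and 2284 lower in replicate 2. Adgre1, which encodes F4/80, was at 35.6 and 53.7 CPM in replicate 1 of WT and CCL5-/- and at 51.8 and 35.3 CPM in replicate 2. Itgam, which encodes CD11b, was at 598 and 580 CPM in replicate 1 and at 180 and 144 CPM in replicate 2. Ccl5, the lists that passed and some single genes are therefore also given within replicate pairs.

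The first comparison asked which genes differ between CCL5-/- and WT F4/80low TAMs. The targeted gene Ccl5 (chromosome 11, 83525778 to 83530518, GRCm38) had 255 and 3976 reads in the WT libraries and 35 and 82 in the CCL5-/- libraries. Its level was 87.3 ± 61.4 CPM in WT and 3.54 ± 0.747 CPM in CCL5-/- (mean ± SD, n = 2). The log2 change was -4.64 (SE 0.69), with -3.39 in the replicate 1 pair and -5.39 in the replicate 2 pair. In this fit Ccl5 did not pass the threshold over all genes (edgeR unadjusted p = 0.00076, adjusted p = 1.0), nor with the replicate term (log2 change -4.58, SE 0.53, adjusted p = 0.099). It passed in DESeq2 (log2 change -4.63, adjusted p = 1.39e-08) and in the authors' deposited table, which gives a log2 change of -1.68 with an adjusted p of 2.6e-05. That table, made from the same counts, also gives smaller changes for Dhx40 (-0.94, against -2.25 in DESeq2) and Camp (-0.75, against -4.24). How its changes were scaled is not given, so their sizes are not compared.

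**Figure D1:**
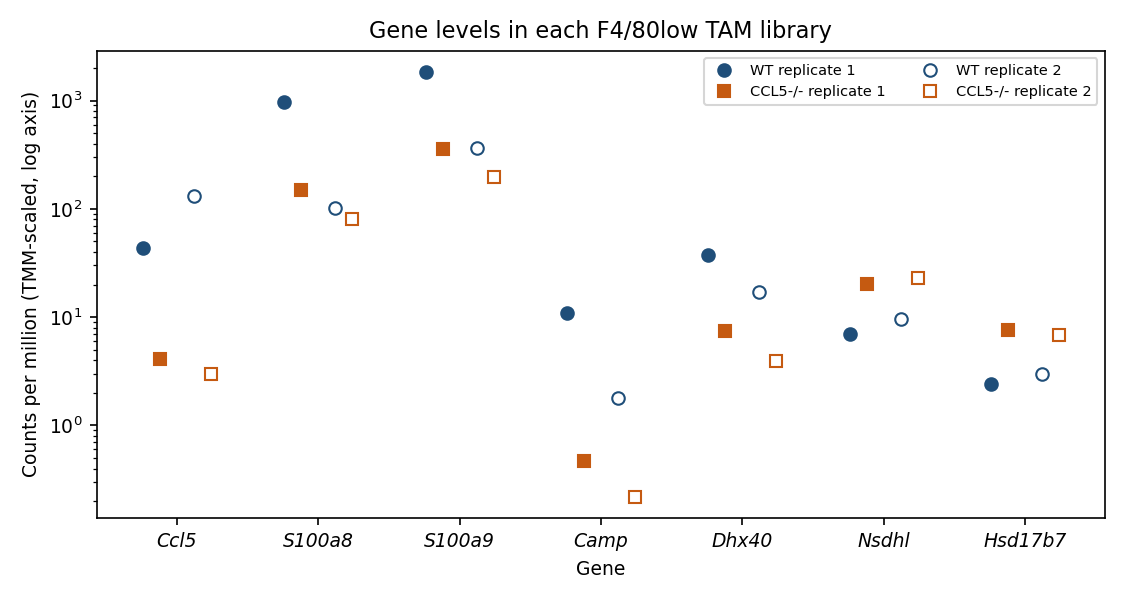
Levels of 7 genes in each F4/80low library, in TMM-scaled CPM on a log axis. Circles are WT, squares are CCL5-/-, filled symbols are replicate 1 and open symbols replicate 2, and there is 1 point per library. Ccl5 lies at 43.8 and 131 CPM in WT and at 4.07 and 3.01 CPM in CCL5-/-.

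No gene passed in the fit without the replicate term. Of 12710 genes, 0 had an edgeR adjusted p under 0.05, and 41 had an unadjusted p under 0.05 (11 higher and 30 lower in CCL5-/-). DESeq2 called 1 gene, Ccl5, and limma-voom called 0. With the replicate term edgeR called 10 genes, all lower in CCL5-/-, and 745 had an unadjusted p under 0.05 (235 higher and 510 lower). Leaving out 1 library moved the count to between 0 and 4 without the term. Without WT replicate 2 it was 4 (Camp, Ccl5, Ngp and Wfdc21), without WT replicate 1 it was 1 (Ccl5) and without CCL5-/- replicate 2 it was 1 (Alb).

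Of the 10 genes that fell with the replicate term, 3 belong to the list of neutrophil markers. Camp, the antimicrobial cathelicidin, had a log2 change of -3.72 (SE 0.61, adjusted p = 0.028), and Olfm4 had -2.87 (SE 0.46, adjusted p = 0.024). Stfa2l1, a stefin protease inhibitor, had -2.12 (adjusted p = 0.0081), and Gm5483, a neighbouring member of the same near-identical family whose reads may not be separable, had -1.64. Il1f9, an interleukin 1 family cytokine, had -1.60 (adjusted p = 0.013). Hp, which encodes haptoglobin, had -1.60, Slpi, an inhibitor of leukocyte proteases, had -1.36, and Rhov had -1.51. Dcn, a matrix proteoglycan made by fibroblasts, had -1.49 (adjusted p = 0.024). The lowest p belonged to Dhx40, an RNA helicase gene on chromosome 11 (86768846 to 86807746), with -2.21 (SE 0.25, adjusted p = 0.0030), and with -2.31 and -2.08 in the replicate pairs. Several of these changes moved when 1 library was left out of the fit without the replicate term. Leaving out 1 library also unbalances the replicate numbers between the genotypes, so the values below mix genotype with replicate number. The replicate 1 and 2 pairs gave -1.50 and -1.67 for Il1f9, -2.57 and -1.58 for Stfa2l1, and -1.84 and -1.16 for Rhov. They gave -2.10 and -1.17 for Gm5483, -3.51 and -1.66 for Olfm4, -1.34 and -1.37 for Slpi, and -1.99 and -1.15 for Hp. Calls with the term favour changes alike in both pairs. Without WT replicate 1 the log2 change was -0.01 for Il1f9, -0.20 for Stfa2l1, -0.25 for Rhov, -0.27 for Gm5483, -0.34 for Olfm4, -0.79 for Slpi and 0.72 for Hp, and it stayed at -2.43 for Camp and -1.60 for Dhx40. Without CCL5-/- replicate 1 it was larger, at -3.16 for Il1f9, -3.83 for Stfa2l1, -2.56 for Rhov and -3.74 for Hp. Without CCL5-/- replicate 2 it was smaller, at -0.77 for Il1f9, -1.73 for Stfa2l1, -1.13 for Rhov and -1.11 for Hp. Dcn was at -0.31 without WT replicate 2, at -0.66 without CCL5-/- replicate 1 and at -2.78 without CCL5-/- replicate 2.

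Among genes chosen by smallest p in edgeR without the replicate term, none passed there, and values alone are given. In the direction of lower levels in CCL5-/-, after Ccl5 and Dhx40, these were the acute-phase gene Saa3 (-1.77, SE 0.47), Wfdc17 (-1.73, SE 0.47; chromosome 11, 83703991 to 83706268) and Osgin1 (-1.26, SE 0.36). In the other direction they were the cholesterol synthesis gene Nsdhl (1.37, SE 0.38), the fatty acid desaturase gene Fads2 (1.18, SE 0.37), the cell cycle regulator Mybl2 (1.02, SE 0.35), the sphingosine-1-phosphate transporter gene Spns2 (1.04, SE 0.37) and Klk10 (0.99, SE 0.36). Both replicate pairs had the same sign for each of these genes, which the choice required, since only genes with non-overlapping groups were taken. The pairs had -2.44 and -1.07 for Saa3 and -2.42 and -1.06 for Wfdc17. None passed in edgeR with the term, but some did in 2 fits with the term added after seeing the data. Wfdc17 passed in DESeq2 (adjusted p = 0.00037) and limma-voom (0.0034), and Saa3 (0.042), Osgin1 (0.015), Nsdhl (0.021) and Fads2 (0.026) passed in limma-voom alone. The chemokine receptor genes Ccr1 and Ccr3 did not pass, with log2 changes of -0.36 (SE 0.50) and 0.01 (SE 0.81). Ccr3 had 0.61 in the replicate 1 pair and -0.71 in the replicate 2 pair.

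The list tests asked which groups of genes shifted together. Of 33 lists, 12 passed camera with a preset correlation, 4 towards higher and 8 towards lower levels in CCL5-/-, and 10 of these also passed with the replicate term. No list passed with an estimated correlation (lowest adjusted p = 0.602, and 0.904 with the replicate term). None passed with fry (lowest adjusted p = 0.939, and 0.464 with the replicate term). With 4 libraries both tests have little to estimate the spread from, so not passing does not show that a list did not shift. Every list result below thus rests on the preset correlation. In the fit without the replicate term, 0 members of any list passed, over all genes or adjusted over the list alone.

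Neutrophil marker genes had lower levels in CCL5-/- (28 tested, median log2 change -1.80, camera adjusted p = 6.6e-28, and 0.602 as adjusted p with an estimated correlation). In both replicate pairs 25 of 28 were lower, with medians of -2.01 and -0.89. With the replicate term 3 members passed over all genes in edgeR, 9 in DESeq2 and 15 in limma-voom, and in edgeR 19, all lower, passed adjusted over the list alone. Camp (-4.26, SE 1.12), Ngp (-3.88), Olfm4 (-3.49) and BC100530 (-3.03) had the smallest p without the term and did not pass there. With the term BC100530 passed in DESeq2 (adjusted p = 0.035) and limma-voom (0.018), and Ngp in limma-voom (0.0034). S100a8 and S100a9, which encode abundant calcium-binding proteins of neutrophils and monocytes, had -2.22 (SE 1.08) and -1.99 (SE 0.88) and did not pass in edgeR. With the term S100a9 passed in DESeq2 (adjusted p = 0.00057) and limma-voom (0.0096). S100a8 had -2.69 in the replicate 1 pair and -0.33 in the replicate 2 pair, and S100a9 had -2.36 and -0.89. Without WT replicate 1 the changes were -0.47 for Ngp, -0.29 for BC100530, -0.39 for S100a9 and 0.19 for S100a8.

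Cholesterol synthesis genes had higher levels in CCL5-/- (23 tested, median 0.66, camera adjusted p = 3.3e-23, and 0.602 as adjusted p with an estimated correlation). In both pairs 22 of 23 were higher, with medians of 0.73 and 0.68. With the replicate term in edgeR 0 passed over all genes and 15, all higher, passed adjusted over the list alone. In limma-voom with the term Nsdhl (1.33, adjusted p = 0.021) and Lss (1.31, adjusted p = 0.049) passed over all genes. Nsdhl, Hsd17b7 (1.41), Lss (1.22, and 0.80 without WT replicate 2) and Sqle (0.81), enzymes of sterol synthesis, had the smallest p. Cell cycle genes (33 tested, median 0.23, adjusted p = 5.1e-05; estimated correlation adjusted p = 0.602) were higher in both pairs for 20 members, with Ccne2 at 1.06 (0.54 without WT replicate 1 and 2.15 without WT replicate 2) and the replication helicase gene Mcm4 at 0.63 (0.37 without CCL5-/- replicate 1). Amino acid and one-carbon genes (26 tested, median 0.33, adjusted p = 0.00030; 0.602 estimated) had 17 members higher in both pairs, with the proline synthesis gene Pycr1 at 1.30 (0.80 without CCL5-/- replicate 2 and 2.34 without WT replicate 2). Glycolysis and hypoxia genes (26 tested, median 0.23, adjusted p = 0.046; 0.710 estimated) had 16, with Car9 at 0.90 (0.36 without CCL5-/- replicate 2 and 1.41 without WT replicate 2), and the list did not pass with the replicate term (adjusted p = 0.058).

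Of the other lists with lower levels, 5 were uneven across the pairs. Type I interferon response genes (30 tested, median -0.39, adjusted p = 1.2e-07; 0.675 estimated) had a median of 0.04 in the replicate 1 pair and -0.86 in the replicate 2 pair, with Ifit1 at -1.06 and Isg15 at -1.11. Without WT replicate 2 these were -0.31 and -0.18. Class II antigen presentation genes (median -0.47, adjusted p = 0.029; 0.833 estimated) had 0.39 and -0.68, with Cd86 at -0.68 (0.11 without WT replicate 2 and -1.18 without WT replicate 1), and did not pass with the replicate term (adjusted p = 0.078). Immune checkpoint genes (median -0.28, adjusted p = 0.030; 0.833 estimated) had 0.11 and -0.62. Inflammatory cytokine genes (median -0.35, adjusted p = 0.00019; 0.602 estimated) had -0.02 and -0.52, with the formyl peptide receptor gene Fpr2 at -0.77. Endothelial markers (median -0.62, adjusted p = 0.0064; 0.602 estimated) had -1.17 and -0.04, with Esam at -1.13 (-0.61 without CCL5-/- replicate 1 and -2.07 without CCL5-/- replicate 2). The pairs were closer for chemokine receptor genes (median -0.49, adjusted p = 0.00017; 0.602 estimated), with -0.53 and -0.71, where Cx3cr1 had -0.96 and Xcr1 -1.23. They were also closer for monocyte markers (median -0.56, adjusted p = 0.00023; 0.698 estimated), with -0.32 and -0.42, where Ms4a4c had -0.75 (-0.39 without WT replicate 2). With the replicate term 1 member of that list passed over all genes, and the list holds Hp, named above. It is thus not separate from the genes called with the term.

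**Figure D2:**
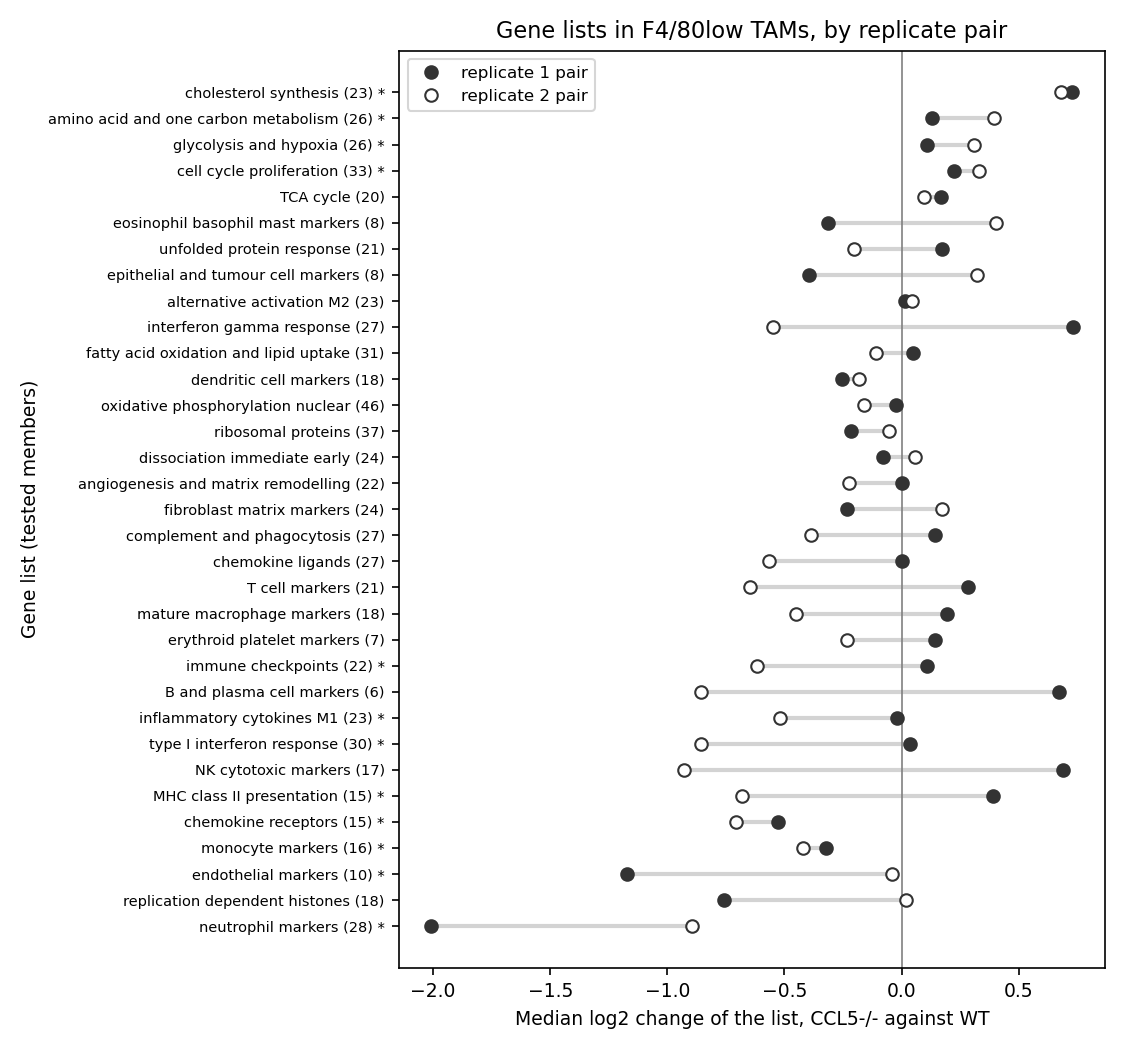
Median log2 change of each tested gene list in F4/80low TAMs, CCL5-/- against WT, with the number of tested members in brackets and an asterisk where camera with a preset correlation gave an adjusted p under 0.05. Filled points are the replicate 1 pair and open points the replicate 2 pair. The neutrophil list lies at -2.01 and -0.89 and the cholesterol synthesis list at 0.73 and 0.68.

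The other 21 lists did not pass without the replicate term. Among markers of other cells, adjusted p-values were 0.057 for T cells (median -0.18), 0.207 for NK cells (-0.46), 0.327 for B and plasma cells (-0.32), 0.0503 for dendritic cells (-0.12), 0.588 for eosinophils, basophils and mast cells (0.02), 0.135 for fibroblasts (-0.15), 0.203 for epithelial and tumour cells (-0.06), 0.582 for red cells and platelets (-0.23) and 0.328 for mature macrophages (-0.18). NK genes had a median of 0.69 in the replicate 1 pair and -0.93 in the replicate 2 pair, and interferon gamma response genes (-0.08, adjusted p = 0.498) had 0.73 and -0.55. Among pathways the adjusted p-values were 0.133 for chemokine ligands (-0.17), 0.948 for alternative activation (-0.08), 0.464 for angiogenesis and matrix remodelling (-0.14), 0.267 for oxidative phosphorylation (-0.13), 0.136 for the TCA cycle (0.02), 0.809 for fatty acid oxidation and lipid uptake (-0.10), 0.558 for complement and phagocytosis (-0.15) and 0.971 for the unfolded protein response (-0.04). Among quality lists, dissociation genes had a median of -0.14 (0.809), ribosomal protein genes -0.13 (0.193) and replication-dependent histone genes -0.67 (0.065). The histone list passed with the replicate term (adjusted p = 0.00010), with -0.76 and 0.02 in the pairs. Such histone genes took 0.17% and 0.11% of counts outside Rn45s in replicate 1 of WT and CCL5-/-, and 0.017% in replicate 2 of either genotype. Their level thus also split by replicate number, and the cause was not tested. The lists of mitochondrially encoded genes and of sex-specific genes had fewer than 5 tested members and were not tested.

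The second comparison set the F4/80hi library labelled CCL5-/- against the one labelled WT, with no replicate check. The targeted gene goes against the labels. Ccl5 was at 145 FPKM in the library labelled CCL5-/- and 15.7 FPKM in the library labelled WT, a log2 change of 3.12. The sample titles, Ccl5 and the read match with F4/80low all put the opposite genotype on each library, and under the titles every F4/80hi difference given here would change sign. Of 11670 genes, 274 were at least 2-fold higher and 184 at least 2-fold lower in the library labelled CCL5-/-. With a pseudocount of 0.1 these were 503 and 351, and with 5 they were 106 and 47.

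By the rule for named genes, all 10 of the highest changes and 2 of the 10 lowest were small RNA genes, short transcripts whose FPKM is unstable. Over all 769 small RNA genes of the table, 13 were listed at 0 in the library labelled WT and at 10 FPKM or more in the other, and 2 the other way round. Leaving out the small RNA genes and those whose estimate the table does not mark as OK, which was decided after their values were seen, the highest changes included neutrophil genes and Mgp. Ngp went from 6.56 to 128 FPKM, Mgp, a matrix protein gene, from 20.5 to 305, Retnlg from 90.3 to 784 and Lcn2 from 26.1 to 222 (library labelled WT first). S100a8 had 1236 and 8045 FPKM and S100a9 had 1487 and 8344 FPKM. The status rule removed Zc3h7a, at 24.2 FPKM in the library labelled WT and listed at 0 in the other. At the other end, genes of liver and gut epithelium (Alb, Fabp1, Ttr) were listed at 0 in the library labelled CCL5-/- and at 53.0, 11.7 and 10.1 FPKM in the library labelled WT. The interferon-induced chemokine gene Cxcl9 had 23.1 FPKM in the library labelled WT and 2.67 in the other, and Ccl8 had 287 and 59.5.

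Of 32 lists measured, 17 had a median outside the central 95% of random lists, 11 above and 6 below. In the library labelled CCL5-/-, neutrophil genes had a median of 1.98 (29 of 29 above 0). Cholesterol synthesis genes had -0.71 (24 of 24 below 0), interferon gamma response genes -0.69 (26 of 27 below 0) and NK genes -0.62 (16 of 16 below 0). Chemokine receptor genes had 0.51, monocyte markers 0.35, histone genes 0.63 and red cell and platelet markers 0.61. Apart from red cell and platelet markers, at 0.14 there, each of these medians has the opposite sign to the F4/80low replicate 1 pair, whose reads these values share.

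Across 10626 genes the F4/80low and F4/80hi changes had a Spearman correlation of -0.60 and a Pearson correlation of -0.62. Genes are not independent replicates. The correlation was -0.85 for the replicate 1 pair and -0.09 for the replicate 2 pair alone, so it was carried by the libraries whose reads match. The 2 replicate pairs of F4/80low had a correlation of 0.04 with each other over 12710 genes.

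**Figure D3:**
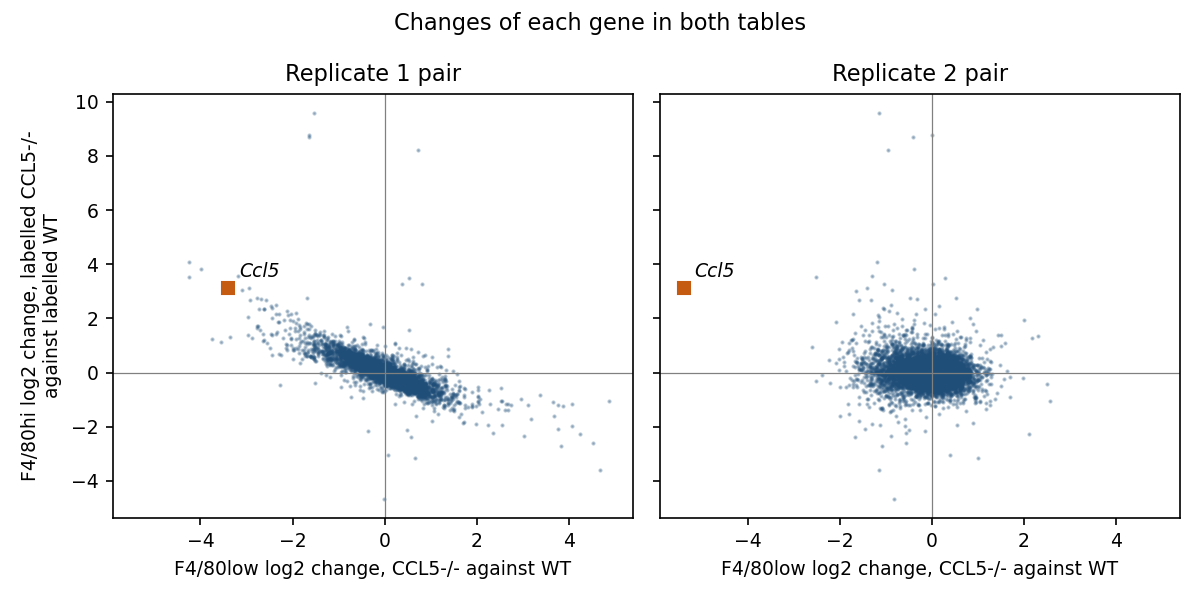
Log2 change of each of 10626 genes in F4/80low (x axis, CCL5-/- against WT, 1 panel per replicate pair) and in F4/80hi (y axis, library labelled CCL5-/- against library labelled WT, FPKM with a pseudocount of 1). Points are genes and the square is Ccl5. The Spearman correlation is -0.85 in the replicate 1 panel and -0.09 in the replicate 2 panel.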

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

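The tests of the shared reads, of the crosswise match and of T and NK cells were chosen after the result was seen. Among the named genes, 11 had both CCL5-/- libraries on the same side of both WT libraries in F4/80low and a change of at least 2-fold the other way between the F4/80hi labels. The difference between gates was not tested. The F4/80hi log2 changes were 3.12 for Ccl5, 3.52 for Camp (2.23 with a pseudocount of 5), 2.49 for S100a9, 2.40 for Saa3, 1.86 for Dhx40 and 1.37 for Slpi, all lower in CCL5-/- in F4/80low. They were -1.19 for Nsdhl, -1.14 for Sqle, -1.13 for Hsd17b7, -1.07 for Klk10 and -1.07 for Ccne2, all higher in CCL5-/- in F4/80low.

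For the first pattern, Ccl5 at 145 FPKM in the F4/80hi library labelled CCL5-/-, transcripts from T or NK cells were considered. Over 32 of their marker genes the median log2 change was -0.501 (SD 0.482) where Ccl5 had 3.12, so these genes were lower where Ccl5 was higher. That cannot decide the question, since T and NK cells of a CCL5-/- mouse would lack Ccl5 too. The shared reads also fix these values. The median chi-square of 0.334, below the 0.455 of independent reads, is consistent with F4/80hi values made from the reads of the F4/80low replicate 1 libraries, with WT and CCL5-/- exchanged. Exchanged genotype labels of the F4/80hi libraries are also consistent with the match, since the median chi-square was 5.354 with the same genotype labels matched, with Ccl5, which follows the F4/80low labels in both pairs, and with the sample titles. The test fixed earlier is void, since the shared reads fix its value, a correlation of -0.831 (bootstrap interval -0.88 to -0.756) across 179 genes called at p under 0.01 with the replicate term. Which gate the shared libraries came from stays open, and no opposite effect of CCL5 in the 2 gates can be read from them. If it was F4/80hi, the F4/80low comparison would mix the gates, with the replicate number standing for the gate.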

How the results depend on the processing

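The fits without Rn45s and Lars2, the replicate block in DESeq2, limma-voom, fry and camera with an estimated correlation, the FPKM values without small RNA genes and the correlations by single pair were chosen after seeing the data. Same-numbered libraries deviated together (correlation 0.73), but the labels do not say that numbers pair the libraries. The count of genes changed in F4/80low was 0 with RLE or upper-quartile factors, without a filter, with the stricter filter, without Rn45s and Lars2, with a 2-fold minimum and in limma-voom. It was 10 with the replicate block, 1 in DESeq2, 23 in DESeq2 with the block, 47 in limma-voom with the block, 1 in the authors' deposited table and 0 to 4 with each library left out. All 10 genes called by edgeR with the block were among the 23 and the 47. Leaving out a library leaves 1 in its group, assumed to vary like the others, and unbalances the replicate numbers between the genotypes. Without the block the simulated 4-fold changes were missed, in a simulation with the replicate difference built in, so a count of 0 there shows little.

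Ccl5 was lower in CCL5-/- in every setting. It passed in DESeq2 (-4.63), DESeq2 with the block (-4.48) and limma-voom with the block (-4.86), and in 2 of the 4 fits with a library left out (-5.21 without WT replicate 1 and -3.64 without WT replicate 2), which ranged from -5.21 to -3.64. Adjusted p-values over the alternatives ran from 1.4e-22 to 1. The number of lists passed was 8 to 14 across scalings, filters, the block and left-out libraries, and 0 with an estimated correlation or fry, with or without the block. In F4/80hi the count of genes changed at least 2-fold, 458, was 854 with a pseudocount of 0.1, 153 with 5 and 243 at FPKM of at least 5. Ccl5 there was 3.20 with a pseudocount of 0.1 and 2.85 with 5. The number of lists outside random lists was 12 to 18. The correlation between gates was -0.64 to -0.060 with a library left out, -0.093 in the replicate 2 pair and -0.85 in the replicate 1 pair, which the shared reads account for. For the other changes the cause was not tested.

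Of 593 values of 57 single gene results, 513 were classed as the same, 44 passed the threshold where they had not, and 26 moved. The other 10 changed sign. No gene at all had passed in the fit without the block, so this says nothing for them. Hp, 1 of the genes that changed sign, passed in edgeR with the block (adjusted p = 0.024). In F4/80low the same meant only an unchanged sign and threshold result, whatever the size. Il1f9 was so classed at -0.015 without WT replicate 1, against -1.54 with all libraries. The size of a change was judged only in F4/80hi. With a library left out, Hp ran from -3.74 to 0.72, S100a8 from -3.08 to 0.19, Ccr1 from -0.85 to 0.032, Ccr3 from -0.68 to 0.56 and Cd86 from -1.18 to 0.11. Ccr3 was also -0.21 with the block, -0.091 in DESeq2 with the block, -0.37 in limma-voom and -0.33 in limma-voom with the block. Depth limits replicate 1 most, with 3857011 and 5243643 counts outside Rn45s.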

Other observations

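The DESeq2 test with the replicate block and the tests of the neutrophil genes and of the genes near Ccl5 were chosen after the results were seen. The list of fatty acid oxidation and lipid uptake genes did not pass (31 tested, median log2 change -0.10, camera adjusted p = 0.809), with 9 members higher and 11 lower in both F4/80low pairs. Its 4 members with the smallest p, picked after their values were seen, went both ways. Scd2, a fatty acid desaturase gene, had log2 changes of 0.92 and 0.96 (edgeR unadjusted p = 0.098), Fasn, the fatty acid synthase gene, 0.55 and 1.09, and Scd1 0.75 and 0.53. Pparg, a lipid-sensing nuclear receptor gene, had -1.46 and -1.67. None passed over all genes in edgeR. DESeq2 with the replicate block called Scd2 (0.96, adjusted p = 0.049).

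The neutrophil genes are the second pattern. The replicate 2 pair alone had a median of -0.894 (median absolute deviation over genes 0.296), and the replicate 1 pair had -2.007. The ribosomal RNA-rich libraries of replicate 1 are not in the replicate 2 pair and cannot account for its drop. That pair is 1 library against 1, however. NK genes (-0.93) and type I interferon response genes (-0.86) fell as far in it, without falling in the replicate 1 pair (0.69 and 0.04), while cholesterol synthesis genes rose (0.68). Whether its neutrophil drop is part of a broader difference between these libraries was not tested. Fewer neutrophils among the sorted CCL5-/- cells and lower expression within the sorted cells cannot be told apart, since either would give the 89.3% of the list lower in both pairs, against 26.5% of all tested genes. S100a8 and S100a9, the most abundant of these transcripts, were at 537 ± 616 and 1100 ± 1038 CPM in WT and 115.5 ± 49.0 and 277.5 ± 114 CPM in CCL5-/- (mean ± SD, n = 2). Monocytes and macrophages can express several of these genes, and an effect of the genotype itself stays open.

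Dhx40 and Wfdc17 are the third pattern, lying 3.24 and 0.17 Mb from Ccl5 on chromosome 11. Within 10 Mb of Ccl5, leaving out all 3 genes, 9 of 183 tested genes (4.92%) had an unadjusted p under 0.01 with the replicate term, against a median of 1.42% in 137 windows of 20 Mb. That share was higher than in 97.1% of windows. It is consistent with strain variants carried with the knocked-out gene, a hypothesis that genotyping could settle. The 9 genes went both ways. They include Slfn4 (-1.10), Slfn1 (-0.74) and Wfdc21 (-2.26), which are expressed in myeloid cells and could also move with cell composition. Slfn10-ps (-1.54) and Myo1d (-1.60) were lower too, and Slfn9 (0.98), Prr11 (0.79), Tmem97 (0.75) and Nle1 (0.68) were higher. An effect of CCL5 loss on Dhx40 was not tested separately.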
